A study of Mus musculus with 20 samples.

How the data were processed

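Total RNA from liver and white adipose tissue (WAT) of wild-type (WT) mice and of mice homozygous for the staggerer allele of Rora (sg/sg) was measured on 20 Agilent whole-genome mouse expression arrays with 1 colour (Cy3). There were 5 arrays for each of the 4 combinations of genotype and tissue, each from a separate mouse of its genotype per the series' design text. Groups and replicate numbers were taken from the sample labels. The labels do not say which fat depot was sampled, nor whether a liver array and an adipose array with the same number came from the same mouse.

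Per the file headers, the deposited intensity of each spot was extracted by the authors with Agilent Feature Extraction 9.5. That program subtracted the background with spatial detrending, applied multiplicative detrending and replaced signals not above background by a surrogate value. No scaling between arrays is recorded in the file headers or in the labels. The deposited value table held linear, uncentred intensities identical to the processed signals of the scanner files, with a highest relative difference of 0 on every array, so neither scale nor centring stayed unknown and no ratio with a direction was involved. Using that table in place of the scanner values therefore changed no value. It is still counted among the alternative settings, where it could not end a call. The median intensities of its columns, replicates 1 to 5 in order, were 57.4, 64.0, 56.6, 65.6 and 55.5 for WT liver and 55.5, 60.0, 64.9, 43.8 and 42.5 for sg/sg liver. For WAT they were 130.9, 220.8, 158.8, 175.7 and 152.0 in WT and 156.4, 117.0, 149.5, 88.8 and 149.9 in sg/sg mice. Surrogate values, which the program fills in for dim spots, make differences between dim probes depend on the fill-in as well as on the RNA, which is the reason for the filter on dim probes described here.

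Each array held 45018 spots, of which 43379 were not controls, for 41174 different probes. Probes were named through the accession in the file where the RefSeq gene table of assembly GRCm38.p6 held it, which gave a gene symbol to 22951 probes (55.7%). A further 11405 probes kept the gene name of the scanner file, and 6818 had neither and were kept under their own identifiers. Probe coordinates are those of the file headers, on mouse build mm7, for which no annotation was used here, so the exon or untranslated region under a probe is not stated.

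The main values were log2 of the deposited processed intensity minus the 75th percentile of the same array. Control spots were left out, spots marked as outliers by the authors' program were set missing (64 values in the tested liver probes and 30 in WAT), and spots of a probe were averaged. A probe was kept in a tissue when it was well above background on at least 4 of the 10 arrays and missing on at most 2. Each gene was represented by its probe with the highest mean. Genotypes were compared in each tissue apart with lmFit and eBayes of limma 3.58.1, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. The test of whether the genotype effect differs between tissues was the interaction term of a limma fit to all 20 arrays. Where no array of a genotype was well above background, the fold is given as a lower bound, the bright group's mean against, per array, the higher of the probe's own signal and the lowest signal among probes well above background.

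Lists of genes (36) were fixed before the data were examined, as were the groups, the tests, the rule for named genes and most of the processing choices that were varied. Each list with at least 5 measured members was tested with camera of limma at a preset correlation of 0.01 between genes. Camera with an estimated correlation was run beside it, as was fry, which asks whether the genes of a list move on balance in a common direction and does not compare them with other genes. No list passed the threshold with an estimated correlation in either tissue, and fry passed 3 lists in liver and 16 in WAT. For each list, members were counted both after adjustment over all genes and adjusted over the list alone. The rule for named genes took all Rora probes. In each tissue it took the 10 largest increases and the 10 largest decreases among called genes whose genotypes were fully separated. From each list past the threshold, and from the clock, macrophage, cytokine and lipid droplet lists in both tissues, it took up to 4 members with the smallest p. It also took the 10 interaction genes with the smallest p, and 6 genes changed in both tissues. A few genes that this rule names are not reported here. A few further list members are named as examples and were chosen after their values were seen.

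The fits were tested on simulated data with 200 genes changed by known amounts in each comparison. The noise was drawn independently for each gene from its spread within groups, without correlation between genes and without slide effects. Far fewer genes were changed than were called in the real data. The simulation thus checks the fits under these conditions only, and gives no false call rate for arrays confounded with slide. For liver, 35.8% of genes changed by a log2 of 0.5, 73.1% of those changed by 1 and 95.5% of those changed by 2 were recovered, with 6 false calls among 17162 unchanged genes. For WAT the shares were 19.4%, 59.7% and 89.4%, with 9 false calls among 22195 genes. For the interaction they were 13.4%, 65.7% and 93.9%, with 8 false calls among 16947 genes.

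The arrays lay on 6 slides, 3 per tissue. In liver, slide 1 held WT replicates 1 to 4, slide 2 held WT replicate 5 with sg/sg replicates 1 to 3, and slide 3 held sg/sg replicates 4 and 5, so that only slide 2 holds both genotypes. In WAT each slide held both genotypes: slide 4 had WT replicates 1 and 3 with sg/sg replicates 2 and 4, slide 5 had WT replicate 5 with sg/sg replicates 3 and 5, and slide 6 had WT replicates 2 and 4 with sg/sg replicate 1. Liver and WAT arrays were also read on different scanners, so tissue and scanner cannot be told apart in levels, and levels are not compared between tissues. Alternatives covered the background correction (normexp with an offset of 50), quantile and median scaling, the filter on dim probes, the mean of a gene's probes, slide as a fixed or random block, the replicate number as a block, array weights, the variance model, and each array left out in turn. R 4.3.3 with the data.table package, version 1.17.8, and statmod 1.5.0 and Python 3.11.15 with matplotlib 3.10.9 were used. The number of arrays limits the precision.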

Results

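Gene expression was measured in the liver and white adipose tissue (WAT) of male C57BL/6 mice, aged 5 months, that had eaten a diet with 35% fat for 6 weeks. The study compared WT mice with staggerer mice (sg/sg), which are homozygous for a natural deletion in Rora, the gene of the nuclear receptor RORα. This receptor is known to activate clock and metabolic genes through ROR response elements. The question is which genes of each tissue depend on RORα on a high fat diet. Each group had 5 mice, with 1 array per mouse and tissue. Between 56.5% and 62.4% of probes were well above background on WT liver arrays, 57.3% to 58.7% on sg/sg liver arrays, 75.3% to 81.1% on WT adipose arrays and 71.9% to 80.3% on sg/sg adipose arrays. The 75th percentile of intensity ran from 817 to 1090 in WT liver, 648 to 901 in sg/sg liver, 1936 to 2598 in WT WAT and 1352 to 2053 in sg/sg WAT. Values below are log2 fold changes of sg/sg over WT with the standard error (SE) and the limma adjusted p, with n = 5 per genotype.

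Rora, the mutated gene, was lower in every sg/sg array than in every WT array, in both tissues and with each of its 3 probes. All 3 probes lie on chromosome 9 of build mm7. At 69410920 to 69410979, the mean log2 level in liver went from 2.05 (SD 0.12) in WT to -0.83 (SD 0.24) in sg/sg mice, a change of -2.88 (SE 0.12, 7.36-fold, adjusted p = 3.2e-06). In WAT the same probe went from 0.05 (SD 0.13) to -2.67 (SD 0.31), a change of -2.72 (SE 0.15, 6.59-fold, adjusted p = 5.5e-05). The probe at 69411020 to 69411079 changed by -2.86 (SE 0.13) in liver and -2.73 (SE 0.15) in WAT. The dimmest probe, at 69417414 to 69417473, changed by -2.75 (SE 0.13, 6.74-fold) in WAT, where it was 0.05 with normexp background correction. In liver this probe was not well above background in any sg/sg array, which makes the change at least 2.14-fold (adjusted p = 0.000102). With slide as a block, Rora was still lower in liver, at -2.92 (SE 0.23, adjusted p = 0.0177). The files do not settle whether these probes lie in the deleted part of the gene, and a probe outside it would not check the genotype.

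**Figure D1:**
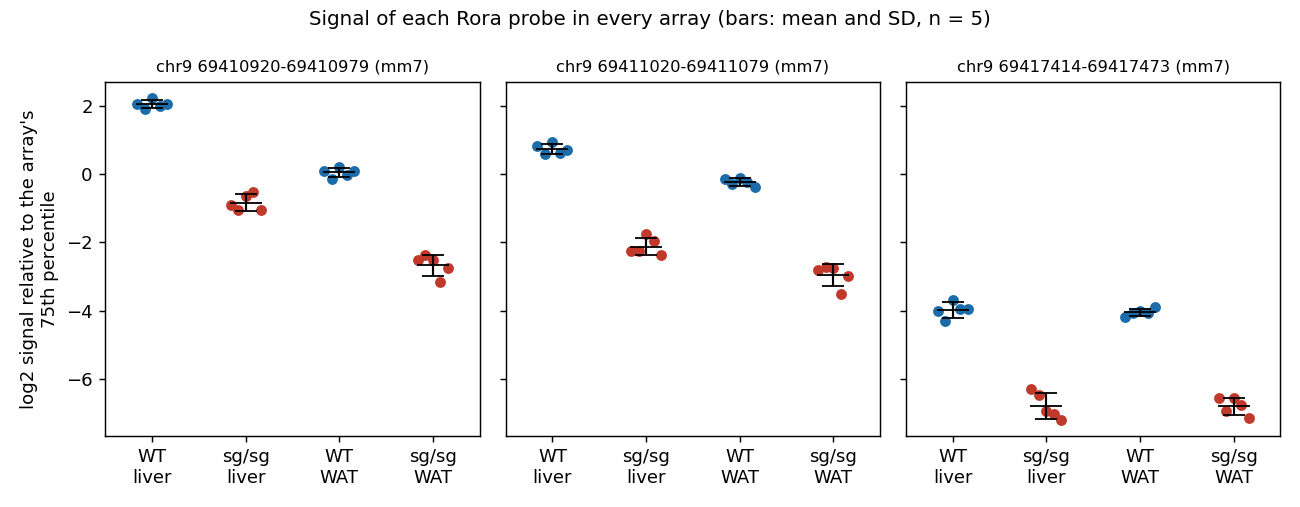
Log2 signal relative to the 75th percentile of the array (vertical axis) for each Rora probe (panels) in every array of the 4 groups (horizontal axis), with points for arrays and bars for the mean and SD (n = 5). For the probe at 69410920 to 69410979, WT liver averages 2.05 and sg/sg liver -0.83, while WT WAT averages 0.05 and sg/sg WAT -2.67.

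In liver of sg/sg mice, 8 of 17 lipid droplet genes and 9 of 25 genes of fatty acid oxidation were lower (adjusted p = 0.547 and 0.7103 for the lists with an estimated correlation), and the oestrogen sulfotransferase Sult1e1 was far higher. Cidea, a lipid droplet protein that promotes the growth of droplets, fell by 5.43 (SE 0.86, 43.2-fold, adjusted p = 0.00757), and its relative Cidec fell by 3.42 (SE 0.69, 10.7-fold, adjusted p = 0.0154). Sult1e1, on chromosome 5 at 87512926 to 87512985, rose by 5.22 (SE 0.43, 37.2-fold, adjusted p = 0.000853). Of 28 macrophage markers 6 were higher (adjusted p = 0.740 for the list with an estimated correlation), with the complement gene C1qa at 0.80 (SE 0.17, 1.75-fold, adjusted p = 0.0168). Of 17362 genes tested with limma, 2822 (16.3%) changed, 1599 higher and 1223 lower, and 337 of them changed at least 2-fold, 140 higher and 197 lower. The count was 1709 without WT replicate 2, 1179 without WT replicate 3, 899 without WT replicate 4, 1719 without sg/sg replicate 3 and 1754 without sg/sg replicate 5. With median scaling the split was 675 higher and 1640 lower. Genotype is largely confounded with slide in liver: with slide as a fixed block limma called 2 genes (1454 at an unadjusted p under 0.05), and within slide 2 alone, with 1 WT and 3 sg/sg arrays, it called 0 (1360 at an unadjusted p under 0.05). The slides of WAT also gave 0 calls each, so a count of 0 within a slide does not by itself separate genotype from slide. Within slide 2, 2757 of the 2822 genes (97.7%) had the same sign, and the median ratio of the change to that over all arrays was 0.733, on genes chosen partly by these same arrays. Since only slide 2 holds both genotypes, each liver fold change with slide as a fixed block is that within slide 2. List medians and list tests in liver with slide as a block therefore rest on 1 WT array against 3 sg/sg arrays, and are no separate check. Genes chosen without slide 2 held up less well: of 1399 genes called between slides 1 and 3, 76.1% had the same sign within slide 2, at a median ratio of 0.216.

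Besides Sult1e1, the largest increases in liver included Tff3, a trefoil peptide of mucosal tissues, at 3.70 (SE 0.66, 13.0-fold, adjusted p = 0.011), with 2.79 within slide 2. Cyp39a1, which hydroxylates an oxysterol on the way to bile acids, rose by 2.21 (SE 0.28, 4.63-fold, adjusted p = 0.00394; within slide 2, 1.53). Acmsd, an enzyme of tryptophan breakdown, was at 2.58 (SE 0.44, 5.98-fold; within slide 2, 1.89) and was well above background in 3 of 5 WT arrays. The digestive proteases Cela2a (2.62, SE 0.49, well above background in 3 of 5 WT arrays; within slide 2, 2.56) and Ctrc (2.42, SE 0.41; within slide 2, 2.32) also rose. The list of exocrine pancreas genes had 2 of 7 measured members higher and none lower, both over all genes and adjusted over the list alone, and did not pass (adjusted p = 0.244). Cpne6 was at 2.89 (SE 0.61) over all arrays but at 0.34 within slide 2, and Pou4f1 was at 2.23 (SE 0.49) against 0.37. Sult1e1 itself was 4.05 within slide 2. The largest decrease was that of Cfd, the serine protease adipsin, at -6.32 (SE 0.86, 80.1-fold, adjusted p = 0.00452; within slide 2, -7.04), which was well above background in 3 of 5 sg/sg arrays. The zinc finger gene Zfp979 was at -4.52 (SE 0.33, 23.0-fold, adjusted p = 0.000439; within slide 2, -3.60), with 2 of 5 sg/sg arrays well above background. Osbpl3, an oxysterol-binding protein, was at -4.05 (SE 0.36, 16.5-fold, adjusted p = 0.00108; within slide 2, -3.40), with 3 of 5 sg/sg arrays well above background. Also among the largest decreases were Rgs16 (-3.81), Stap1 (-3.45), Ppp1r3g (-3.43), a glycogen-targeting subunit of a phosphatase, and the melatonin receptor Mtnr1a (-3.00), which were -4.84, -3.07, -3.01 and -2.98 within slide 2. Of the sg/sg arrays, 1 of 5 was well above background for Stap1, 3 of 5 for Ppp1r3g and 4 of 5 for Mtnr1a.

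The lipid droplet and lipolysis list had 17 members measured in liver, of which 8 fell, 0 rose and 9 did not pass; adjusted over the list alone 11 fell. Its median was -0.63 (camera adjusted p = 4.4e-06; adjusted p = 0.547 with an estimated correlation), and -0.63 with slide as a block. The droplet coat proteins Plin4 (-2.66, SE 0.43, 6.32-fold, adjusted p = 0.00829; within slide 2, -2.15) and Plin2 (-0.88, SE 0.16, 1.84-fold, adjusted p = 0.0106; within slide 2, -0.83) fell. Within slide 2, Cidea was -3.49 and Cidec -3.17. Of 25 genes of fatty acid oxidation 9 fell, 0 rose and 16 did not pass, and 11 fell adjusted over the list alone. The median was -0.39 (adjusted p = 3.3e-08; adjusted p = 0.7103 with an estimated correlation), and -0.59 with slide as a block. Acot2, a mitochondrial acyl-CoA thioesterase, was at -1.76 (SE 0.28, 3.39-fold, adjusted p = 0.00803; within slide 2, -1.96). Ppara, the receptor that drives this pathway, was at -0.65 (SE 0.13, 1.57-fold, adjusted p = 0.0128; within slide 2, -0.69), and the oxidation enzymes Ehhadh and Acadm were at -0.78 and -0.41. Of 22 genes of fatty acid and triglyceride synthesis 4 fell, 1 rose and 17 did not pass, with 6 lower and 1 higher adjusted over the list alone. The median was -0.69 (adjusted p = 0.00417; adjusted p = 0.740 with an estimated correlation), and -0.51 with slide as a block. Mogat1, which makes diacylglycerol, was at -2.79 (SE 0.54, 6.91-fold; within slide 2, -2.21) and Thrsp, a lipogenic protein, at -2.35 (SE 0.56, 5.11-fold; within slide 2, -3.02), while the desaturase Scd2 was at 0.34 (SE 0.09). Cholesterol synthesis and uptake had 1 of 24 genes lower (adjusted p = 0.0766), bile acid and sterol transport 1 of 17 higher (adjusted p = 0.611), lipoproteins 2 of 23 higher (adjusted p = 0.193), and glucose metabolism and insulin signalling 2 higher and 1 lower of 22 (adjusted p = 0.827). Genes of oxidative phosphorylation had 3 of 32 lower and 0 higher, with 2 lower adjusted over the list alone. Their median was -0.02 (camera adjusted p = 0.0766, and 0.762 with an estimated correlation). With slide as a block the list passed camera (lower, median -0.13, adjusted p = 6.5e-05), but that test rests on the 1 WT array of slide 2.

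Clock genes were lower in liver: 5 of 19 fell, 0 rose and 14 did not pass, with 7 lower adjusted over the list alone. The median was -0.39 (adjusted p = 0.00076; adjusted p = 0.547 with an estimated correlation), and -0.42 with slide as a block. Dbp, an output factor of the clock, was at -1.70 (SE 0.39, 3.25-fold, adjusted p = 0.0214; within slide 2, -2.04). The repressors Cry2 and Nr1d2 were at -0.81 (SE 0.14) and -0.52 (SE 0.14). Bhlhe41, also a repressor, was not well above background in any sg/sg array and was at least 1.78-fold lower (adjusted p = 0.00297). Within slide 2 Bhlhe41 was at -1.31, and over all settings its smallest log2 change was -0.32, under that bound. The list of ROR targets described outside this study had 1 of 20 members higher and 1 lower and did not pass (adjusted p = 0.827). Its median was 0.06, opposite in sign to the direction of the test. Immediate early genes had 6 of 18 lower and 12 not past, with 7 lower and 1 higher adjusted over the list alone. Their median was -0.38 (adjusted p = 0.0353; adjusted p = 0.740 with an estimated correlation) and -0.08 with slide as a block, where the list did not pass (adjusted p = 0.187). The growth-induced factors Egr1 (-2.36, SE 0.37, 5.13-fold; within slide 2, -2.29) and Fos (-1.27, SE 0.28; within slide 2, -1.38) were among them.

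Xenobiotic metabolism had 4 of 28 genes lower, 1 higher and 23 not past, with 4 lower and 2 higher adjusted over the list alone. The median was -0.22 (adjusted p = 0.0429; adjusted p = 0.547 with an estimated correlation), and -0.38 with slide as a block. Sult1b1, a sulfotransferase, was at -1.10 (SE 0.10, 2.14-fold, adjusted p = 0.00108; within slide 2, -0.98), and the receptor Nr1i2 was at -0.54 (SE 0.10; within slide 2, -0.73), whereas Sult1e1, a member of the same list, rose. Female-biased liver genes had 2 of 14 lower, 1 higher and 11 not past, with the same counts adjusted over the list alone. Their median was -0.65 (adjusted p = 0.0429; adjusted p = 0.740 with an estimated correlation), and -1.17 with slide as a block. The thioesterase Acot3 fell by 3.48 (SE 0.59, 11.1-fold, adjusted p = 0.00936; within slide 2, -4.88), with 4 of 5 sg/sg arrays well above background, while Cyp39a1 rose. Male-biased liver genes had 3 higher and 1 lower of 17 (adjusted p = 0.357).

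Markers of other cell types also differed in liver. Of 28 macrophage markers 6 rose, 0 fell and 22 did not pass, and 8 rose adjusted over the list alone. The median was 0.45 (adjusted p = 0.00076; adjusted p = 0.740 with an estimated correlation), and 0.42 with slide as a block. The scavenger receptor Cd68 was at 0.68 (SE 0.16, 1.60-fold, adjusted p = 0.024; within slide 2, 0.53), and C1qa was 0.60 within slide 2. Of 17 endothelial markers 6 rose and 11 did not pass, with 6 higher adjusted over the list alone. Their median was 0.17 (adjusted p = 0.0353; adjusted p = 0.740 with an estimated correlation), and 0.37 with slide as a block. Egfl7 was at 0.57 (SE 0.09) and the tight junction gene Cldn5 at 0.60 (SE 0.11), with 0.57 and 0.56 within slide 2. Hepatocyte genes had 3 of 21 higher and 18 not past, 4 higher adjusted over the list alone, with a median of 0.18 (adjusted p = 0.0429; adjusted p = 0.740 with an estimated correlation). With slide as a block that median was 0.02, the test pointed down and the list did not pass (adjusted p = 0.671), nor did it pass with normexp, quantile or median scaling. The tyrosine aminotransferase Tat was at 0.88 (SE 0.16; within slide 2, 0.70), Hpd at 0.50 (within slide 2, 0.05) and transferrin, Trf, at 0.38 (within slide 2, 0.14). Adipocyte genes had 3 of 13 lower and 10 not past, with 6 lower and 2 higher adjusted over the list alone. Their median was -0.17 (adjusted p = 0.0429; adjusted p = 0.740 with an estimated correlation), and -0.41 with slide as a block; Cfd and Cidec were among the members that fell. Cell cycle genes had 1 of 19 lower, Tyms at -0.56 (SE 0.11; within slide 2, -0.28), also adjusted over the list alone. Their median was -0.35 (adjusted p = 0.0216; adjusted p = 0.774 with an estimated correlation), and -0.03 with slide as a block, where the list did not pass (adjusted p = 0.671). Nor did it pass without WT replicate 2 (adjusted p = 0.177), which stood apart for these genes at 1.43 against a mean of -0.10 for the other WT arrays. Of the further probes of Tyms, 1 was at -0.53 (adjusted p = 0.0145) and the other at 0.79 (adjusted p = 0.0746). Of 24 alternative settings, the hepatocyte list passed in 7, adipocytes in 11 and xenobiotic metabolism in 13. Female-biased liver genes and immediate early genes passed in 14 each, and endothelium and cell cycle in 17 each. The settings include the deposited value table, which repeats the main values. Among named liver genes, Trf lost its call in 14 of 22 settings besides slide as a fixed block, Hpd in 13, Nr1d2 in 12, Scd2 in 9, Cd68 in 7 and Pou4f1 and Cxcl14 in 6 each.

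Inflammatory gene lists did not pass in liver with all arrays and no slide block. Cytokines and chemokines had 3 higher and 1 lower of 29 (adjusted p = 0.827), with Il1a, an early inflammatory cytokine, at 0.95 (SE 0.13, 1.93-fold, adjusted p = 0.00452; within slide 2, 0.59) and Cxcl14 at -1.15. Toll-like receptors and inflammasome genes had 5 of 23 higher (adjusted p = 0.193), and acute phase proteins 5 higher and 1 lower of 24 (adjusted p = 0.0766). The interferon response (adjusted p = 0.107) and MHC class II and costimulation (adjusted p = 0.258) did not pass either, but with slide as a block the interferon response passed (lower, adjusted p = 0.0364). Neutrophil markers had 1 of 7 higher (adjusted p = 0.244), T and NK cell markers 1 of 21 higher (adjusted p = 0.184, but past with slide as a block, higher, adjusted p = 0.0215) and B cell markers 2 higher and 1 lower of 13 (adjusted p = 0.745). The passes of the interferon and T and NK cell lists with slide as a block rest on the 1 WT array of slide 2.

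**Figure D2:**
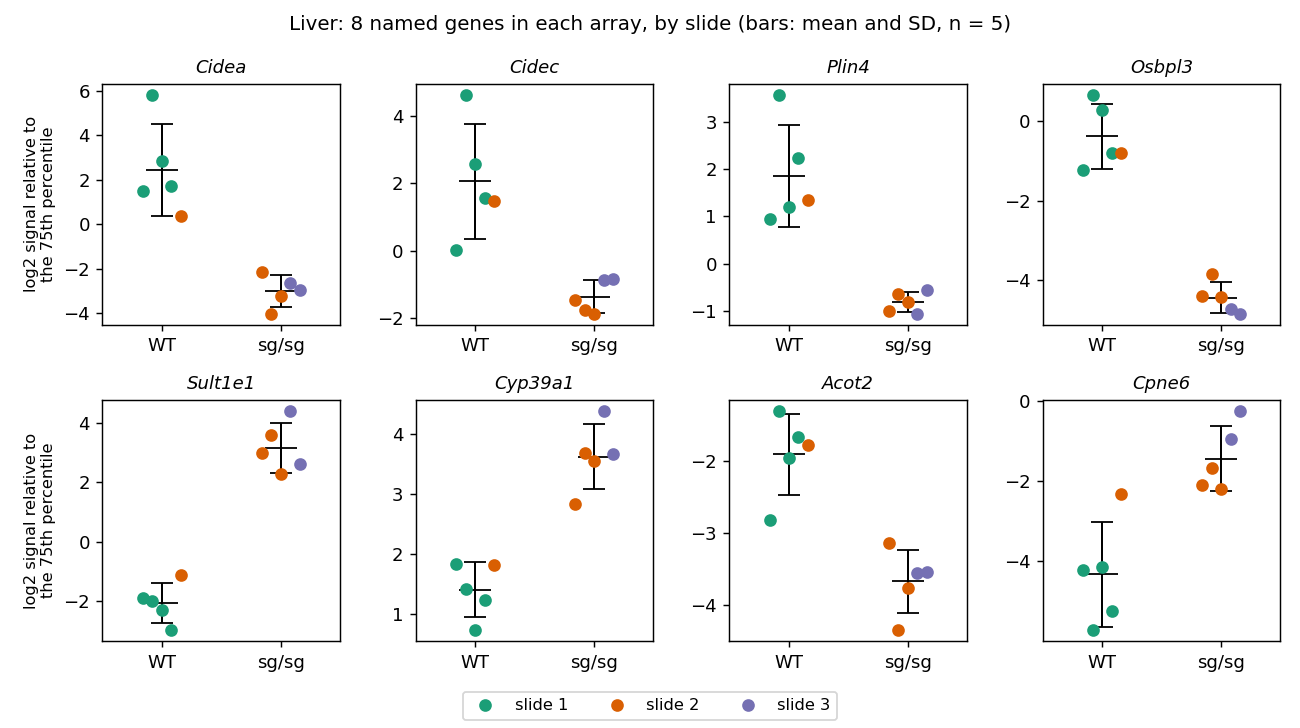
Log2 signal relative to the 75th percentile (vertical axis) of 8 named genes in the 5 WT and 5 sg/sg liver arrays (horizontal axis), coloured by slide, with bars for the mean and SD. Sult1e1 rose by 5.22 over all arrays and by 4.05 within slide 2, while Cpne6 was at 2.89 over all arrays and 0.34 within slide 2.

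In WAT of sg/sg mice, 24 of 34 cytokines and chemokines, 18 of 30 macrophage markers, 21 of 36 matrix genes and 23 of 24 cell cycle genes were lower. Of glucose and insulin signalling genes 12 of 21 were higher and 2 lower, and 9 of 22 lipid synthesis genes and 16 of 32 genes of mitochondrial respiration were higher; with an estimated correlation the adjusted p of these lists ran from 0.112 to 0.707. The chemokine Ccl2, which attracts monocytes, fell by 2.60 (SE 0.27, 6.08-fold, adjusted p = 0.000578), and the cytokine Tnf fell by 1.56 (SE 0.16, 2.95-fold, adjusted p = 0.000558), but was at -0.02 (adjusted p = 0.981) with normexp background correction. Itgax, the surface integrin CD11c, fell by 3.496 (SE 0.40, 11.3-fold, adjusted p = 0.000701), although a further probe was at -0.82 (adjusted p = 0.125). Irs1, the adaptor of the insulin receptor, rose by 1.11 (SE 0.19, 2.16-fold, adjusted p = 0.00312), and Pparg, the nuclear receptor of fat cell differentiation, rose by 0.86 (SE 0.15, 1.82-fold, adjusted p = 0.00303), with 0.67 (adjusted p = 0.077) with normexp. Of 22395 genes tested with limma, 5334 (23.8%) changed, 3223 higher and 2111 lower, and 1653 changed at least 2-fold, 710 higher and 943 lower. With slide as a fixed block 4722 genes were called, 4358 of them also without it. Within slides 4, 5 and 6 limma called 0 genes each, with 3676, 3608 and 2826 at an unadjusted p under 0.05. In those slides 100%, 99.8% and 99.9% of the 5334 genes had the same sign, at median ratios of 1.06, 0.794 and 1.12, on genes chosen partly by these same arrays. Of the 1589, 2219 and 2538 genes called without slide 4, 5 or 6, 96.2%, 99.0% and 95.1% had the same sign within the slide left out, at median ratios of 0.923, 0.660 and 1.06. With normexp background correction 1432 genes were called, 742 higher and 690 lower. WT replicate 2 and sg/sg replicate 4 correlated least with their groups; without both, an alternative chosen after seeing the data, 7243 genes were called, 4882 of them also with all arrays.

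The largest increases in WAT included Acsm3, a medium-chain acyl-CoA ligase, at 3.92 (SE 0.55, 15.1-fold, adjusted p = 0.00143), and Pon1, a paraoxonase carried on lipoproteins, at 2.98 (SE 0.49, 7.91-fold, adjusted p = 0.00276). Fn3k, a kinase that removes sugar adducts from proteins, on chromosome 11 at 121559459 to 121559518, rose by 2.63 (SE 0.17, 6.21-fold, adjusted p = 9.51e-05), with 2.75, 2.1996 and 2.90 within slides 4, 5 and 6. Ppp1r3b, a glycogen-targeting subunit, was at 2.57 (SE 0.29, 5.92-fold; 2.99, 2.40 and 2.18 within slides). Cyp1a1, a xenobiotic oxidase, was at 3.25 (SE 0.56) and was well above background in 2 of 5 WT arrays. The largest decreases included Tph2, a serotonin-synthesis enzyme, at -5.88 (SE 0.37, 58.9-fold, adjusted p = 8.79e-05; -5.51, -5.26 and -6.76 within slides), and Mmp12, the elastase of macrophages, at -5.61 (SE 0.78, 48.9-fold, adjusted p = 0.00138). Ubd, a ubiquitin-like modifier, was at -5.34 (SE 0.43, 40.4-fold, adjusted p = 0.000223). Atp6v0d2, a proton pump subunit, was at -4.96 (SE 0.64, 31.2-fold). Mstn, a growth inhibitor of muscle, was at -5.03 (SE 0.57), with 1 of 5 sg/sg arrays well above background. The aldose reductase relative Akr1b7 and the lactate dehydrogenase Ldhc were not well above background in any sg/sg array and were at least 78.8-fold (adjusted p = 0.00428) and at least 28.0-fold lower (adjusted p = 0.00717). With normexp the calls of Mstn (-0.19, adjusted p = 0.858), Akr1b7 (adjusted p = 0.222), Ldhc (adjusted p = 0.369), Atp6v0d2 (-2.53, 0.103) and Cyp1a1 (1.90, 0.114) ended. Over all settings the smallest log2 changes of Akr1b7 and Ldhc were -2.43 and -1.57, well under the lower bounds given for them.

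Of 34 cytokines and chemokines measured in WAT, 24 fell, 0 rose and 10 did not pass; adjusted over the list alone 25 fell and 1 rose. The median was -1.29 (adjusted p = 8.1e-15; adjusted p = 0.112 with an estimated correlation), -1.35 with slide as a block and -1.45, -1.09 and -1.34 within slides 4, 5 and 6. Il1rn, the antagonist of the interleukin-1 receptor, was at -4.40 (SE 0.48, 21.1-fold) and Saa3, an inflammatory amyloid, at -3.14 (SE 0.30, 8.81-fold). Of 30 macrophage markers 18 fell, 0 rose and 12 did not pass, with 21 lower and 1 higher adjusted over the list alone. The median was -0.82 (adjusted p = 4.1e-11; adjusted p = 0.290 with an estimated correlation), -0.85 with slide as a block and -1.11, -0.61 and -1.16 within slides. Gpnmb, a membrane glycoprotein of lipid-laden macrophages, was at -3.91 (SE 0.54, 15.0-fold, adjusted p = 0.0013), Lgals3 at -2.04 (SE 0.24, 4.11-fold) and Mpeg1 at -2.03 (SE 0.27, 4.10-fold). Lyz2, the brightest of these markers in WT mice, was at 0.00 (SE 0.09, adjusted p = 0.990). Of 13 genes of MHC class II and costimulation 8 fell and 5 did not pass, with 10 lower adjusted over the list alone. Their median was -0.81 (adjusted p = 4.3e-08; adjusted p = 0.290 with an estimated correlation), and -0.94 with slide as a block; Ciita, the master activator of class II genes, was at -1.37 (SE 0.18, 2.59-fold) and H2-DMb1, which helps load peptides, at -1.44 (SE 0.16, 2.72-fold). Of 26 Toll-like receptor and inflammasome genes 15 fell and 11 did not pass, with 16 lower adjusted over the list alone. Their median was -0.43 (adjusted p = 2.0e-06; adjusted p = 0.290 with an estimated correlation), and -0.43 with slide as a block. Tlr6 was at -1.56 (SE 0.19), Tlr8 at -2.17 (SE 0.38) and the inflammasome protease Casp1 at -1.03 (SE 0.18); with normexp Tlr6 was at -0.90 (adjusted p = 0.181) and Tlr8 at -0.02 (adjusted p = 0.988). Acute phase proteins had 5 of 23 lower, 1 higher and 17 not past, with 6 lower and 3 higher adjusted over the list alone. Their median was -0.33 (adjusted p = 0.00601; adjusted p = 0.295 with an estimated correlation), and -0.41 with slide as a block. Lbp, which carries lipopolysaccharide, was at -1.25 (SE 0.12, 2.38-fold), Saa1 at -2.35 (SE 0.25, 5.11-fold), and ceruloplasmin, Cp, was the member that rose, by 0.97. A further probe of Saa1 was at -1.66 (limma adjusted p = 0.0649).

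Other immune lists did not pass in WAT without a slide block. The interferon response had 4 of 30 genes lower (adjusted p = 0.227, but past with slide as a block, lower, adjusted p = 0.0479), T and NK cell markers 1 higher and 2 lower of 26 (adjusted p = 0.299), B cell markers 2 higher and 2 lower of 17 (adjusted p = 0.789) and neutrophil markers 3 of 13 lower (adjusted p = 0.260). Endothelial markers had 2 of 17 higher (adjusted p = 0.299), with a median of 0.16.

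Cell cycle genes fell in WAT: 23 of 24 were lower and 1 did not pass, also adjusted over the list alone. The median was -1.65 (adjusted p = 1.3e-18; adjusted p = 0.290 with an estimated correlation), -1.61 with slide as a block and -1.57, -0.75 and -2.32 within slides 4, 5 and 6. Mcm5, part of the replicative helicase, was at -1.60 (SE 0.18, 3.03-fold, adjusted p = 0.000721), the spindle checkpoint kinase Bub1 at -2.37 (SE 0.30, 5.17-fold, adjusted p = 0.00101) and the mitotic kinase Aurkb at -1.76 (SE 0.22). With normexp Bub1 was at -0.56 (adjusted p = 0.521) and Aurkb at -0.79 (adjusted p = 0.233). Of 36 extracellular matrix genes 21 fell, 1 rose and 14 did not pass, with 23 lower and 2 higher adjusted over the list alone. The median was -0.66 (adjusted p = 8.1e-11; adjusted p = 0.112 with an estimated correlation), and -0.70 with slide as a block. The metalloproteinase Adam8 was at -3.41 (SE 0.36) and the collagen gene Col5a2 at -1.20 (SE 0.15), though Col5a2 did not pass with all 20 arrays in a common fit (adjusted p = 0.0575).

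Several metabolic lists were higher in WAT. Of 21 genes of glucose metabolism and insulin signalling 12 rose, 2 fell and 7 did not pass, with 13 higher and 2 lower adjusted over the list alone. The median was 0.66 (adjusted p = 0.00947; adjusted p = 0.290 with an estimated correlation), 0.66 with slide as a block and 0.61, 0.62 and 0.80 within slides 4, 5 and 6. The glucose transporter Slc2a4, GLUT4, was at 1.29, the glycogen-targeting Ppp1r3c at 1.66 (SE 0.35) and the pyruvate dehydrogenase kinase Pdk2 at 0.87 (SE 0.15). Of 22 genes of fatty acid and triglyceride synthesis 9 rose and 13 did not pass, with 12 higher adjusted over the list alone. The median was 0.58 (adjusted p = 0.00481; adjusted p = 0.707 with an estimated correlation), and 0.54 with slide as a block. The carboxylase Acacb was at 1.69 (SE 0.26, 3.22-fold, adjusted p = 0.00192) and the lipogenic factors Srebf1 and Mlxipl were at 0.90 (SE 0.15) and 1.17 (SE 0.22). Lipid droplet and lipolysis genes had 6 of 17 higher and 11 not past, with 7 higher adjusted over the list alone. Their median was 0.26 (adjusted p = 0.0218; adjusted p = 0.511 with an estimated correlation), and 0.25 with slide as a block; G0s2, an inhibitor of the lipase ATGL, was at 1.26 (SE 0.14, 2.39-fold), Pnpla2, which encodes that lipase, at 0.49 (SE 0.09, 1.40-fold), and Cidea at 1.31 (SE 0.21, 2.48-fold). Genes of oxidative phosphorylation had 16 of 32 higher and 16 not past, with 18 higher adjusted over the list alone. Their median was 0.39 (adjusted p = 2.7e-05; adjusted p = 0.684 with an estimated correlation), and 0.41 with slide as a block. Sdha of complex II was at 0.62 (SE 0.12, 1.53-fold) and Ndufa9 of complex I at 0.51 (SE 0.11). A further probe of Sdha was at 0.30 (limma adjusted p = 0.163). Adipocyte genes had 7 of 21 higher, 1 lower and 13 not past, with 9 higher and 1 lower adjusted over the list alone. Their median was 0.39 (adjusted p = 0.00947; adjusted p = 0.707 with an estimated correlation), and 0.32 with slide as a block. Plin1, the coat of fat cell droplets, was at 0.66 (SE 0.14) and Cebpa at 0.60 (SE 0.13), while the hormone leptin, Lep, fell by 0.84. WT replicate 2 stood apart for the adipocyte genes, at -0.71 against a mean of -0.08 for the other WT arrays, and without it the adipocytes list still passed (higher, adjusted p = 0.0293). The synthesis, lipid droplet, adipocyte and oxidative phosphorylation lists did not pass with normexp background correction, nor did Pnpla2 (0.26, adjusted p = 0.237), Plin1 (0.47, 0.131), Cebpa (0.41, 0.209), Sdha (0.43, 0.136) and Ndufa9 (0.32, 0.169). The lists of fatty acid and triglyceride synthesis and of lipid droplet and lipolysis also did not pass with array weights (adjusted p = 0.0916 and 0.0883), without sg/sg replicate 4 (0.1059 and 0.1061) or without both outlying arrays (0.187 and 0.0798). With quantile scaling the lipid droplet (0.1295) and adipocyte (0.117) lists did not pass, and without the filter on dim probes the lipid droplet list did not (0.0609). Mesothelial genes, of the cells that cover visceral fat, had 7 of 12 higher and 5 not past, with 9 higher adjusted over the list alone. Their median was 1.07 (adjusted p = 0.00118; adjusted p = 0.511 with an estimated correlation), 0.90 with slide as a block and 0.98, 0.32 and 1.68 within slides; Nkain4 was at 1.41 (SE 0.28, 2.66-fold) and the mesothelial transcription factor Wt1 at 1.04 (SE 0.24, 2.06-fold). With all 20 arrays in a common fit Cidea (adjusted p = 0.164), Wt1 (0.0737) and Plin1 (0.136) did not pass, and with the mean of probes Ppp1r3c did not (0.0658). Further probes kept the direction but did not pass limma for Ppp1r3c (1.38, adjusted p = 0.201), Pnpla2 (0.71, 0.102) and Cebpa (0.58, 0.0683).

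Clock genes did not pass camera as a list in WAT but passed fry (higher, adjusted p = 0.0058), with 6 higher, 1 lower and 13 not past of 20, the same counts adjusted over the list alone, and a median of 0.36 (adjusted p = 0.0986). The repressors Bhlhe40 and Nr1d1 were at 1.62 (SE 0.23, 3.07-fold) and -1.09 (SE 0.20, 2.13-fold), and the kinase gene Csnk1e was at 0.73 (SE 0.09), with 0.54 (adjusted p = 0.0561) with normexp. ROR targets described outside this study had 5 higher and 1 lower of 21, and did not pass camera (adjusted p = 0.451) but passed fry (higher, adjusted p = 0.0023). Fatty acid oxidation had 5 higher and 1 lower of 25 (camera adjusted p = 0.440, fry adjusted p = 0.0352). Neither test passed cholesterol synthesis and uptake, with 2 of 24 higher (camera adjusted p = 0.926), or thermogenic genes, with 3 higher and 4 lower of 19 (camera adjusted p = 0.443).

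**Figure D3:**
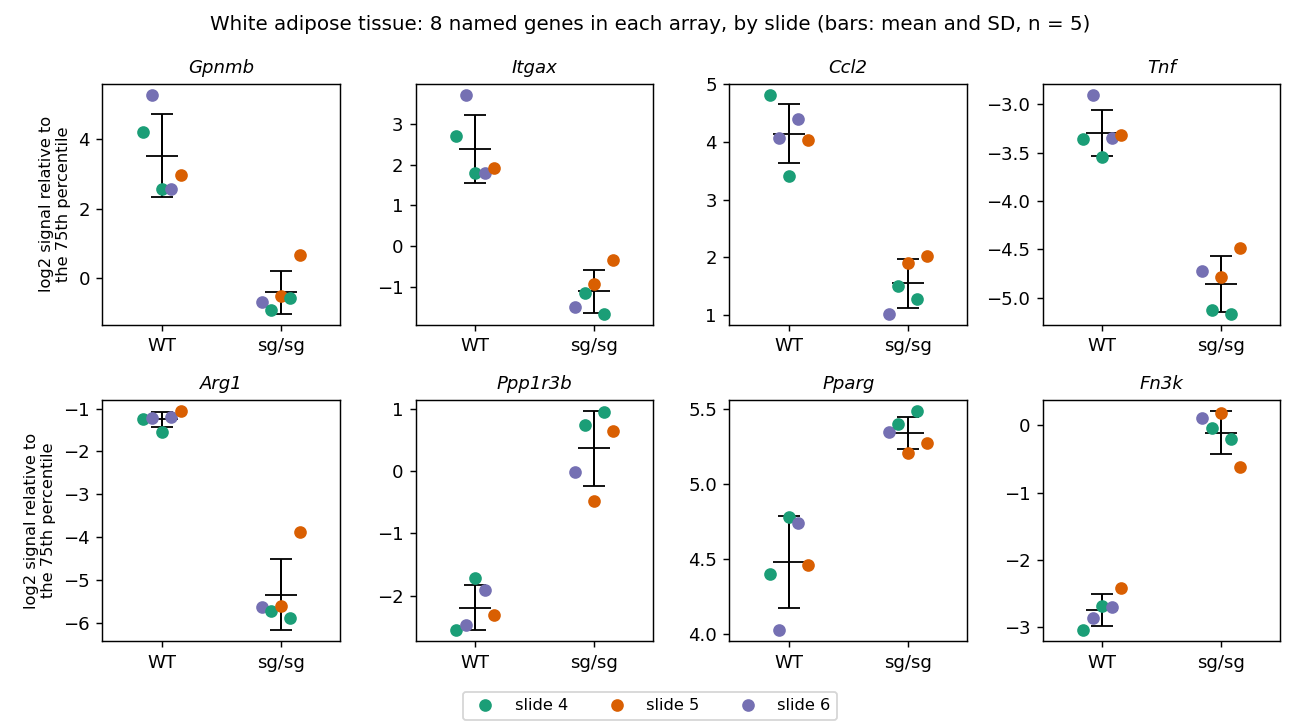
Log2 signal relative to the 75th percentile (vertical axis) of 8 named genes in the 5 WT and 5 sg/sg adipose arrays (horizontal axis), coloured by slide, with bars for the mean and SD. Ccl2 fell by 2.60 and Gpnmb fell by 3.91, while Fn3k rose by 2.63.

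**Figure D4:**
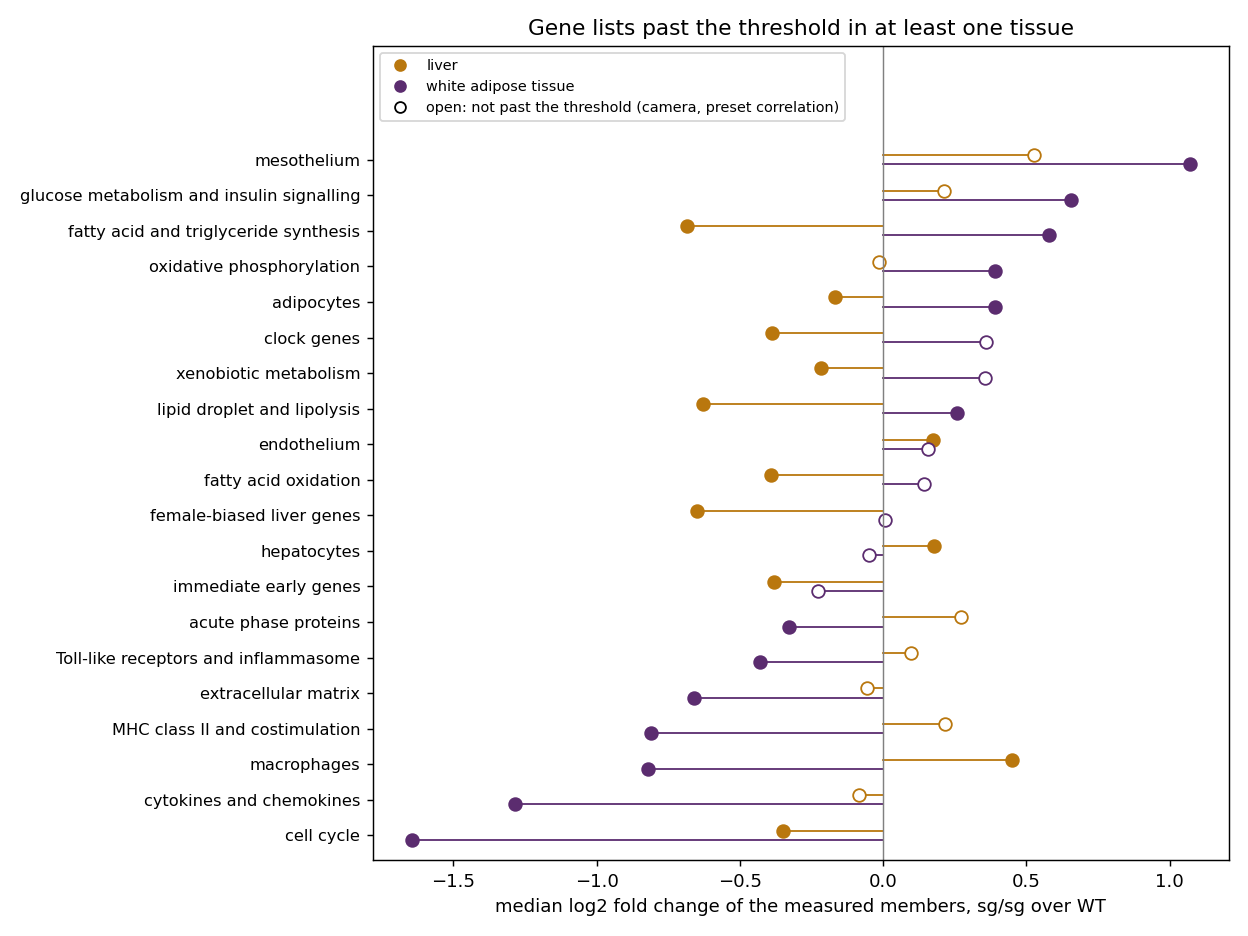
Median log2 fold change of sg/sg over WT (horizontal axis) of each gene list past the camera threshold in at least 1 tissue (vertical axis), with filled points past the threshold and open points not past it. Macrophage markers lie at 0.45 in liver and -0.82 in WAT, and fatty acid and triglyceride synthesis at -0.69 and 0.58.

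The macrophage, lipid synthesis and lipid droplet lists had medians of opposite sign in the tissues, where the liver side is largely confounded with slide. The change of the macrophage marker Cd68 was lower in WAT than in liver by a log2 difference of -2.56 (SE 0.38, adjusted p = 0.000139), and that of Acacb was higher in WAT by 3.25 (SE 0.60, adjusted p = 0.000864). Cidea fell in liver and rose in WAT, a difference of 6.74 (SE 0.93, adjusted p = 9.2e-05). Of 17147 genes tested, 3677 had a genotype effect that differed between tissues, 1992 with the WAT effect above the liver effect and 1685 below; 5954 passed an unadjusted p under 0.05. The fold changes had opposite signs for 2975 of the 3677, counted whether or not a gene was called in either tissue. Choosing genes by a large difference favours opposite signs. Among genes kept in both tissues, 353 were called in both with opposite directions. With median scaling the split was 2229 above and 1144 below, and with slide as a fixed block 710 genes were called, 667 of them also without it. Fn3k had the smallest p, with a difference of 2.55 (SE 0.19, adjusted p = 9.5e-07) and a liver change of 0.09 (SE 0.09, adjusted p = 0.4996) that was -0.02 with median scaling. Arg1, the urea cycle arginase that marks some macrophages, differed by -4.21 (SE 0.39, adjusted p = 3.8e-06), with a fall by 4.10 in WAT (SE 0.35, 17.2-fold; with normexp -1.93, adjusted p = 0.0952) and 0.10 (SE 0.16, adjusted p = 0.683) in liver. Zfp979 differed by 4.24 (SE 0.38, adjusted p = 3.2e-06), since it fell in liver and was at -0.28 (SE 0.16, adjusted p = 0.225) in WAT. Fam13a, a locus gene of fat distribution, differed by 2.87 (SE 0.25) and Acot4, a peroxisomal thioesterase, by 2.72 (SE 0.26). Camera on the interaction, chosen after seeing the data, passed 14 lists, of which none passed with an estimated correlation. Median differences of WAT minus liver included -1.34 for macrophages (adjusted p = 9.3e-13; adjusted p = 0.178 with an estimated correlation) and -1.08 for cytokines and chemokines (adjusted p = 2.8e-06; adjusted p = 0.178 with an estimated correlation). In the other direction they included 0.94 for fatty acid and triglyceride synthesis (adjusted p = 2.3e-05; adjusted p = 0.422 with an estimated correlation) and 0.93 for clock genes (adjusted p = 0.000139; adjusted p = 0.178 with an estimated correlation).

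Among the genes changed in both tissues were Ubd, Stap1 and Osbpl3, which fell in both, and Cidea, which fell in liver and rose in WAT. Observed counts are given beside those for independent lists, without a test of the difference. Among 17150 genes kept in both tissues, 240 were higher in both against 232 for independent lists, and 141 were lower in both against 113. In opposite directions, 163 were higher in liver and lower in WAT against 151, and 190 were lower in liver and higher in WAT against 173. In all, 381 genes changed in the same direction and 353 in opposite directions (51.9% the same). With median scaling these counts were 233 and 232, with normexp 180 and 176, and without the filter on dim probes 123 and 112. With slide as a fixed block only 2 genes were called in liver at all. Across genes, which are not independent replicates, Pearson's r of the fold changes was 0.0312. Ubd fell in both tissues, by 2.09 (SE 0.51, 4.25-fold; within slide 2, -2.14) in liver and 5.34 in WAT. Stap1, a signalling adaptor, and Osbpl3 also fell in both, with -3.45 and -4.05 in liver and -2.06 (SE 0.44) and -1.19 (SE 0.25) in WAT, where with normexp they were at -1.18 (adjusted p = 0.216) and -0.66 (adjusted p = 0.223). A further probe of Osbpl3 in WAT was at -0.79 (limma adjusted p = 0.0849). Accsl rose in both, at 2.93 (SE 0.68; within slide 2, -0.27) in liver, where 1 of 5 WT and 3 of 5 sg/sg arrays were well above background, and 2.55 (SE 0.52) in WAT. Cfd fell in liver and rose by 0.85 (SE 0.25, 1.80-fold, adjusted p = 0.0356) in WAT. There the call ended with slide as a block (adjusted p = 0.0513) and in 14 of 22 other settings, with log2 fold changes from 0.56 to 0.93 over all settings. Genes flanking Rora on chromosome 9 did not pass as a list in liver (3 higher and 6 lower of 50, adjusted p = 0.595) or in WAT (5 higher and 11 lower of 54, adjusted p = 0.189).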

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

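The values within slides for named genes, fry in other splits of the arrays, the comparison of tissues for gene lists, the tests of an adipocyte share and of fewer macrophages, and the test on genes changed at least 2-fold across slides were chosen only after the results were seen.

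Genotype effects that differed between liver and WAT in the test of the difference itself made up 3677 genes. The 10 with the smallest p had log2 differences of WAT minus liver of 2.55 for Fn3k, -1.81 for Dna2 (with normexp -0.85, adjusted p = 0.249), 2.16 for Syde2, 2.87 for Fam13a, 4.24 for Zfp979, 2.65 for Dennd2d, -1.42 for Kcnq1, -4.21 for Arg1, 1.97 for Sfxn1 and 2.72 for Acot4. Kcnq1 has a further probe in WAT that moved the other way (0.92, against -0.95). Among lists, the median difference was 0.93 for clock genes, 0.65 for lipid droplet and lipolysis, 0.94 for fatty acid and triglyceride synthesis, 0.53 for fatty acid oxidation, 0.61 for glucose metabolism and insulin signalling, 0.83 for adipocytes and 0.43 for oxidative phosphorylation. It was -0.68 for acute phase proteins, -1.34 for macrophages, -1.08 for cytokines and chemokines, -0.48 for Toll-like receptors and inflammasome, -1.08 for MHC class II and costimulation, -0.30 for extracellular matrix and -0.95 for cell cycle. With an estimated correlation none of these list differences passed camera. Of 100 splits of the genotypes within each tissue, 1, the real one, gave as many genes as 3677, and the highest of the others gave 1930. A chance split of the arrays would thus seldom give as many genes. The slides are not excluded, since the liver side of the real split nearly follows them, and with slide as a fixed block the count was 710.

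Single arrays stood apart from their groups by Dixon's test in 27 of 388 groups, where chance flags about 1 in 20 groups, or 19.4. Of these, 2 concern whole arrays: the mean correlation with its own group was lowest for WT WAT replicate 2 (ratio of gap to range 0.761) and sg/sg WAT replicate 4 (0.782). Among lists, WT liver replicate 2 stood apart in cell cycle genes (0.878) and WT WAT replicate 2 in adipocyte genes (0.770). Among liver genes, WT replicate 2 stood apart for Mogat1 (0.724), Mcm3 (0.906), Mcm5 (0.834), Birc5 (0.809) and Ubd (0.758), WT replicate 1 for Abcd2 (0.734) and Acot4 (0.773), WT replicate 3 for Ppp1r42 (0.734) and WT replicate 5 for Accsl (0.839). In sg/sg liver, replicate 2 stood apart for Cela2a (0.826), Ctrc (0.743) and Ehhadh (0.823) and replicate 5 for Tgfb1 (0.718). In WAT, WT replicate 2 stood apart for Acsm3 (0.733), Accsl (0.743) and Cfd (0.887) and WT replicate 3 for Cidea (0.786). In sg/sg WAT, replicate 2 stood apart for Cyp1a1 (0.785), replicate 4 for Ttc36 (0.718) and replicate 5 for Atp6v0d2 (0.822), Gpnmb (0.743), Dennd2d (0.876) and Arg1 (0.853).

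The genes changed in liver follow genotype and slide together. Of 100 splits of the 10 arrays, drawn from 126 possible, 1, the real one, gave as many genes as 2822, and the highest other gave 1. A chance split would thus seldom give as many, but the real split also nearly follows the slides. Genes called across slides 1 and 3 had a median ratio of 0.216 (95% bounds 0.190 to 0.240) within slide 2. For the WAT slides 4, 5 and 6 in turn the ratio was 0.923, 0.660 and 1.06. Liver genes changed at least 2-fold across slides had 0.105 (bounds 0.0741 to 0.134). These bounds come from 1000 resamples of genes, which are not independent, and do not measure the spread between mice or slides. By the ratios, a slide batch may account for much of the liver calls. The comparison within slide 2 rests on 1 WT array. Without WT replicate 2, 57.5% of the 2822 genes were still called, all with the same sign and at a median ratio of 0.948. Leaving out some other arrays ended as many calls or more. For these genes, chosen partly by that array, the kept signs and sizes argue against WT replicate 2 alone making the pattern. A genotype effect stays open for genes such as Sult1e1, whose log2 fold change kept its direction within slide 2 (4.05). Sult1e1 was, however, not called with slide as a block (limma adjusted p = 0.257).

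The lower macrophage markers in WAT are weighed next. A larger adipocyte share that dilutes every other cell type alike is argued against, since the endothelial median lay above the macrophage median by 0.977. The bounds of that difference, 0.626 to 1.55, come from resampling list members and do not measure the spread between mice. The 2 outlying arrays are argued against as the whole cause, since the median without both was -0.77 against -0.82. Fewer macrophages may be a candidate explanation, with 25 of 30 measured markers below 0, but Lyz2, the brightest in WT mice, was at 0.00 (SE 0.09) while Ctss, next in brightness, was at -1.64, so fewer cells and a changed state of the cells cannot be told apart.

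Genes changed in the same direction in both tissues could come from a chromosome segment around Rora carried from the donor stock. Within 20 Mb of Rora 7 of 306 genes (2.29%) changed in the same direction in both, against 373 of 16718 (2.23%) elsewhere, a ratio of 1.03 (bounds 0.490 to 2.15, Fisher's exact p = 0.845). The bounds are too wide to exclude a contribution for these few genes, which stays open, as does an effect of RORα itself.

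Camera at the preset correlation passed 12 lists in liver, and 29 of 100 splits gave as many, the highest other 20. In WAT it passed 13 lists, and 42 of 100 splits gave as many, the highest other 21. Each other split holds the genotypes in unequal shares and so keeps part of the genotype difference. These counts therefore do not decide whether chance could account for the number of lists in either tissue. By fry, 3 lists passed in liver and 2 of 100 splits gave as many, but the other of these gave 9 and the real split nearly follows the slides, so chance is not firmly excluded for the liver count. By fry 16 passed in WAT and 1 split, the real one, gave as many (highest other 2), so a chance split would seldom give the WAT count. For genes in WAT, 1 of 100 splits, the real one, gave as many as 5334, and the highest other gave 9, so a chance split would seldom give as many. The other splits mix the genotypes, which raises the spread within their groups and lowers their gene counts.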

How the results depend on the processing

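Leaving out both outlying WAT arrays was chosen after seeing the data. Pairs of a called gene and a setting were counted with slide as a fixed block left aside, and with the unchanged deposited value table included. Of 1906 such pairs in WAT 1842 kept the call, 63 lost it and 1 turned. In liver 1351 of 1526 kept it and 175 lost it, and for the tissue difference 318 of 319 kept it. Counts of genes changed in liver, 2822 with the main choices, were 982 without a filter on dim probes (894 shared, more genes tested), 2 with slide as a fixed block, 1742 with slide as a random block, 337 at least 2-fold and 0 by limma within slide 2 (1360 at an unadjusted p under 0.05). With slide as a fixed block 1 of 70 named liver genes was still called, 68 lost the call and 1 turned; the standard errors were larger with a median ratio of 1.77. Lists past the threshold in liver numbered 7 with probes above background on all arrays, 6 with array weights, 0 with an estimated correlation by camera and 3 by fry. Without each array in turn liver genes ran from 899 to 3132 and lists from 6 to 15. The liver count was 1709 without WT replicate 2, 1179 without WT replicate 3, 899 without WT replicate 4, 1719 without sg/sg replicate 3 and 1754 without sg/sg replicate 5, and the lists numbered 6 without WT replicate 2, 7 without WT replicate 5 and 7 without sg/sg replicate 2. In WAT 1432 genes were called with normexp (1276 shared), 1653 at least 2-fold and 0 by limma within slides 4, 5 and 6 (3676, 3608 and 2826 at an unadjusted p under 0.05), and 0 lists passed with an estimated correlation; leaving out each array gave 3931 to 6973 genes and 12 to 15 lists. The tissue difference, 3677 genes, was 2279 with normexp, 710 with slide as a fixed block, 5686 with array weights and 1404 at least 2-fold, and 3006 to 4534 without each array. Genes changed the same way in both tissues, 381, were 180 with normexp, 233 with median scaling and 123 without the filter. Replicate numbers did not pair the arrays of the 2 genotypes, with correlations from -0.088 to 0.183 in liver and -0.159 to 0.103 in WAT. As a block they gave 1430 genes in liver (1269 shared) and 3438 in WAT (3353 shared). Between liver and WAT, arrays of the same number correlated from -0.037 to 0.152 in WT and from -0.071 to 0.109 in sg/sg mice. This does not settle whether they came from the same mouse. With genotype and replicate number as a fixed or random mouse block, all 10 named interaction genes kept the call. With normexp, Rora in liver was -0.48 (69417414 to 69417473) and -2.47 (69411020 to 69411079). In WAT it was 0.049 (69417414 to 69417473), -1.91 (69411020 to 69411079) and, for 69410920 to 69410979, -2.00. An added offset shrinks the changes of dim probes. The offset of 50 was not varied, so its share in these differences was not tested. Changes that turned sign were Rbp4 in liver with quantile scaling (-0.024), Fn3k in liver with median scaling (-0.017), the mean of probes (-0.015) and slide as a fixed block (-0.0027), Arg1 (-0.11) and Accsl (-0.27) in liver with slide as a fixed block, and Ticam2 in WAT with normexp (0.53). Beyond the filter and the arrays left out, the cause was not tested. The median of all liver genes was 0.05 and -0.06 with median scaling, and that of WAT genes was 0.09 and 0.41 with normexp. Dim signals limit the precision of genes not well above background.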

Other observations

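Gene families grouped by the root of their symbols, a grouping and a test chosen after seeing the data, showed further changes in WAT. Of 308 zinc finger genes with the root Zfp, many of them repressors of transcription, 87 rose and 8 fell (median 0.24, camera adjusted p = 0.000279; adjusted p = 0.571 with an estimated correlation). Of 10 Hoxa genes, which hold positional identity, 7 rose and 0 fell (median 0.76, adjusted p = 0.00884; adjusted p = 0.584 with an estimated correlation). Of 32 kinesin genes with the root Kif, motors of which several act in mitosis, 12 fell and 2 rose (median -0.42, adjusted p = 0.000355; adjusted p = 0.571 with an estimated correlation), but with normexp background correction, which raised the median of all WAT genes, the Kif median was 0.18. Of 8 colony stimulating factor genes and their receptors with the root Csf, 6 fell (median -0.83, adjusted p = 0.00417; adjusted p = 0.741 with an estimated correlation). With normexp the medians of the Zfp, Hoxa and Csf families were 0.49, 1.09 and -0.45, against a median of all WAT genes that normexp moved from 0.09 to 0.41, so the Zfp median then lay little above that of all genes. The medians of these families kept their sign with quantile and median scaling and with slide as a block.

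In liver, 6 of 18 peroxisome assembly genes with the root Pex fell (median -0.21, adjusted p = 0.0148; adjusted p = 0.922 with an estimated correlation), as did 6 of 12 carboxylesterase genes with the root Ces (median -0.48, adjusted p = 0.0289; adjusted p = 0.922 with an estimated correlation). Ucp1, the uncoupling protein of brown fat, named after its values were seen, was not well above background in any WT liver array and was so in 4 of 5 sg/sg arrays, at least 1.56-fold higher (adjusted p = 0.0191). Its list of thermogenic genes did not pass in liver, with 3 higher and 2 lower of 16 (camera adjusted p = 0.958), and another member, Cidea, fell. The change of Ucp1 within slide 2 was not examined, so whether it follows genotype or slide was not tested. With slide as a block the Pex median was -0.24 and the Ces median -0.64, and both kept their sign with normexp, quantile and median scaling. There were 222 families tested in liver and 272 in WAT. Also past the threshold in liver was the root Olfr, with 28 of 232 genes higher and 0 lower (median 0.27, camera adjusted p = 0.0289). Among all liver genes tested, 1599 of 17362 were higher. The Olfr median was 0.24 with normexp, 0.17 with quantile scaling, 0.16 with median scaling and 0.12 with slide as a block. The root Acot passed as well, with 4 of 11 genes lower (median -0.34, camera adjusted p = 0.0289). With an estimated correlation the camera adjusted p of Olfr and of Acot was 0.922.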
